A study of Mus musculus with 12 samples.

How the data were processed

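Ear skin RNA from 12 libraries, 4 groups of 3, was sequenced after library preparation with the NEBNext Ultra kit, per the labels' protocols. Per the submitters' processing notes, TopHat2 2.0.8, Bowtie2 2.1.0 and Cufflinks 2.1.1 were used with the mouse build mm9; the role and settings of each are not given in the sources used here. Each deposited table holds a gene symbol and 1 value per gene for 23234 symbols. The values were taken as the FPKM (fragments per kilobase of transcript, scaled to the fragments mapped) that the authors deposited; the file headers print no unit, and the unit was inferred from Cufflinks and from the range of the values. The reference annotation at hand is of another build than mm9, so no coordinates are given. Strandedness is not given, so overlapping and antisense genes cannot be told apart, and members of near-identical families (Sprr2, Krtap, Klk) may share reads.

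Groups were taken from the labels. The labels do not say whether the libraries of a group came from separate animals, so p-values measure only the spread between these samples, which may be technical. Replicate numbers follow deposit order and pair nothing. Library codes fall into 2 series: the first holds 2 libraries of each wild type group, the second the third library of each wild type group and all 3 of VDRcKO_Oxarol. The series was treated as a possible batch although the labels do not call it one.

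No read counts were used here. The low values of a library are multiples of the value of 1 read, and comparing them between libraries gave read numbers relative to WT_PBS replicate 3, with 87.7% to 96.6% of ratios on the expected steps; a factor of 2 remains possible for any library. The method was tested on simulated data with known log2 ratios of up to 3 between libraries. Beyond that range lay, among others, all VDRcKO_Oxarol libraries (3.08 to 3.63 from the deepest) and WT_Oxarol replicate 3 (3.95). Some zeros look like failed estimates: in WT_PBS replicate 3, Krt2, Scd1, Ubb, G3bp2, Phactr2 and Rps27 are listed at 0 against medians of 3241, 1974, 2814, 25.2, 13.7 and 1685 FPKM. Genes at 0 are therefore described only as listed at 0.

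Values were tested as log2(FPKM + 1) in R 4.3.3 with limma 3.58.1. Genes with at least 1 FPKM in at least 3 of the 12 libraries were kept, 14059 in all. One fit of 4 group means (8 residual degrees of freedom) with an intensity trend in the variance gave 5 comparisons, each adjusted by Benjamini-Hochberg at 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates changes of low genes, and errors are moderated standard errors unless named SD. In simulated data with 200 changed genes among 14059, the test found 80.3% of 2-fold and 97.0% of 4-fold changes between WT_Oxarol and WT_PBS, with 4.83% false calls, and 81.0%, 96.4% and 4.37% between VDRcKO_Oxarol and WT_Oxarol. The simulation draws normal values with each gene's own spread.

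A total of 35 gene lists (17 pathway, 18 cell type) was written before the data were examined. Each was tested with limma's camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists of a comparison. The rule for named genes was fixed at the same time. For the ointment and genotype comparisons it took Vdr, Cyp24a1, the 10 largest increases and 10 largest decreases (adjusted p under 0.05, at least 1 FPKM in the higher group, no overlap of libraries) and up to 4 members of each list by adjusted p; for the others it took the 5 largest each way, or the 5 smallest p where fewer than 5 genes passed. Genes named for one comparison could be given in the others.

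The alternatives tried were a pseudocount of 0.1, no filter, a filter of 5 FPKM, quantile normalization, median-of-ratios scaling, fits of only the 2 groups compared, the library series as a term, the first series alone, a robust variance model, array weights and leaving out each library. Added after seeing the data were zeros of abundant genes set to missing, short RNA genes left out, the hair follicle level as a term, and WT_untreated replicate 3 and WT_PBS replicate 3 left out together. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.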

Results

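Gene expression was measured by RNA sequencing in ear skin of C57BL/6J mice aged 8 to 12 weeks, in 12 libraries forming 4 groups of 3. Wild type (WT) ears were untreated, treated with phosphate-buffered saline (PBS), or treated with 100 mg of Oxarol, an ointment holding 2.5 µg of the active vitamin D3 analogue maxacalcitol. The fourth group received the same ointment and is labelled K5-Cre;VDR f/f, a genotype in which Cre recombinase, driven by the keratin 5 promoter, removes part of the vitamin D receptor gene Vdr in basal keratinocytes. It is called VDRcKO_Oxarol below, after its label. Treated ears were taken 1 day after application. Each library listed 23234 gene symbols, of which 17323 to 19478 had a value above 0. From the steps of the low values, WT_PBS replicate 3 held the most reads, and the other 11 libraries held 0.065 to 0.212 of its reads. Pearson correlations of log2 values within groups ranged from 0.931 to 0.966.

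The gene-level Vdr value in the libraries labelled VDRcKO_Oxarol was not lower than in wild type. Vdr stood at 23.6, 25.0 and 18.0 FPKM in these 3 libraries, against 7.20 ± 0.61 (SD, n = 3) in WT_Oxarol and 9.62 ± 0.46 (SD, n = 3) in WT_PBS. The rise over WT_Oxarol was 1.49 ± 0.21 (SE) on the log2 scale (limma, adjusted p = 0.00558), which goes against the direction the genotype label would give. A value over the whole gene also counts exons outside the deleted part and cells without Cre, so it does not check the deletion. Cyp24a1, the enzyme that degrades active vitamin D and a standard target of the receptor, separated the groups by label: it stood at 66.2, 599 and 458 FPKM in WT_Oxarol and at 0, 0.271 and 0.175 FPKM in VDRcKO_Oxarol.

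The first comparison asked which genes respond to the ointment in wild type skin, against PBS, which is not the base of the ointment. Cyp24a1 rose most, by 8.02 ± 0.62 (SE, log2, n = 3 and 3; adjusted p = 0.000566), from 0.0219 ± 0.0084 FPKM (SD) with PBS. Slc39a4, an intestinal-type zinc importer, rose by 4.95 ± 0.53 to 57.3 ± 39.3 FPKM (SD, n = 3). The kallikrein serine proteases of the epidermis Klk12, Klk13 and Klk6 rose by 3.64 ± 0.46, 3.58 ± 0.41 and 2.85 ± 0.35. Among cornified envelope precursors, Sprr2a2 rose by 4.09 ± 0.43 and Sprr2b by 3.70 ± 0.30. Tslp, the epithelial cytokine that starts type 2 inflammation, rose by 1.65 ± 0.28 (adjusted p = 0.0440), from 4.69 ± 1.02 to 17.8 ± 7.46 FPKM (SD, n = 3).

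Further genes that rose with the ointment were the suprabasal keratin Krt1 (1.71 ± 0.21), repetin Rptn (0.72 ± 0.10), Slc37a2 (0.84 ± 0.14), Serpina9 (2.72 ± 0.35), Fxyd4 (1.95 ± 0.30) and Crot, a peroxisomal carnitine acyltransferase (1.74 ± 0.30). The secretoglobin Scgb1a1 fell by 1.49 ± 0.23, the lipase Lipn fell by 1.15 ± 0.18, Clca3 fell by 0.88 ± 0.10 and the amino acid transporter Slc6a14 fell by 0.81 ± 0.12. 2010109I03Rik and Pstpip1 fell by 0.78 ± 0.13 and 0.74 ± 0.11. Mir1224 and Mir744 were also called lower, and both were listed at 0 in all 3 WT_Oxarol libraries. Above 0, their values were higher where read depth was lower. Mir744 stood at 6.59 FPKM in WT_PBS replicate 3, the deepest library, and at 29.3 in WT_PBS replicate 2 (0.113 of its reads). Mir1224 stood at 12.3 and 54.7 FPKM in these 2 libraries. A few reads per library would give such values, so both calls may rest on very few reads. Vdr itself changed by -0.38 ± 0.21 (adjusted p = 0.787). Defb14, a beta-defensin, differed by 1.43 ± 0.26 (adjusted p = 0.0661), Stfa1 by 2.48 ± 0.59 (adjusted p = 0.158), the basal keratin Krt15 by -0.84 ± 0.18 (adjusted p = 0.103) and Il18 by -0.75 ± 0.16 (adjusted p = 0.126), all without passing.

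By gene list, 3 of 24 measured kallikreins and inhibitors rose over all genes tested, while 7 were higher and 2 lower adjusted over the list alone. The list as a whole did not pass camera (adjusted p = 0.177). Of 11 small proline-rich (Sprr) genes, 2 rose and 10 had a change above 0, with a median of 0.86 (camera adjusted p = 1.33e-06), which was 0.56 without WT_PBS replicate 3. Of 15 known receptor targets from other tissues, 2 rose over all genes and 4 adjusted over the list alone (median 0.20, camera adjusted p = 0.00574); this median was 0.09 without WT_PBS replicate 1 and 0.03 and 0.10 without WT_Oxarol replicates 2 and 3. None of 31 cell cycle genes passed singly, but all 31 had a change above 0 (median 0.25, camera adjusted p = 2.14e-05). This list no longer passed without WT_PBS replicate 3 (median 0.09) or WT_Oxarol replicate 1 (0.14). Late cornified envelope genes had a median of -0.26 (adjusted p = 0.000354) with 0 of 18 called, but did not pass without WT_PBS replicate 2 (-0.11), and stood at -0.42 and -0.39 without WT_PBS replicate 3 and WT_Oxarol replicate 1. Macrophage markers had a median of 0.23 (adjusted p = 2.14e-05) with 0 of 20 called. Basal keratinocyte genes had a median of -0.22 (adjusted p = 0.00654), cartilage genes 0.28 (adjusted p = 0.00553) and sebaceous gland genes 0.22 (adjusted p = 0.00929), with no member called. Single libraries ended each of these: the basal keratinocyte list did not pass without WT_Oxarol replicate 2 (-0.16), the cartilage list without WT_PBS replicate 2 (0.12) or WT_Oxarol replicates 2 (0.18) and 3 (0.16), and the sebaceous gland list without WT_PBS replicate 1 (0.14) or WT_Oxarol replicate 2 (0.10). Without WT_Oxarol replicate 1 the cartilage and sebaceous gland medians were 0.44 and 0.34, and without WT_PBS replicate 3 the latter was 0.35. Hair follicle genes had a median of -0.72 (adjusted p = 0.00929), which turned to 0.53 in the first library series alone and to 0.24 without WT_PBS replicate 3, a library with a high hair follicle level. It did not pass without WT_Oxarol replicate 2 (-0.45) or 3 (-0.42), and was -1.33, -1.11 and -1.14 without WT_PBS replicates 1 and 2 and WT_Oxarol replicate 1. With an estimated correlation, the adjusted p was 0.641 for the receptor targets and 0.748 for the Sprr, cell cycle, late cornified envelope, macrophage, basal keratinocyte, cartilage, sebaceous gland and hair follicle lists.

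In total, limma called 43 of 14059 genes between WT_Oxarol and WT_PBS, 35 higher and 8 lower, and 15.9% of genes had no overlap between the groups, where chance gives 10%. A fit of these 6 libraries alone called 0 genes (1401 at an unadjusted p under 0.05), with adjusted p = 0.0758 for Cyp24a1 (7.59e-09 to 0.195 over its alternatives), the first library series alone called 8, and calls were lost under 18 of 26 alternatives for Slc37a2 and Crot, 16 for Tslp and 2010109I03Rik, 13 for Lipn and Scgb1a1 and 11 for Slc6a14. The count was 15, 27 and 20 without WT_PBS replicates 1, 2 and 3, 132, 21 and 13 without WT_Oxarol replicates 1, 2 and 3, and 26 and 28 without VDRcKO_Oxarol replicates 2 and 3.

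**Figure D1:**
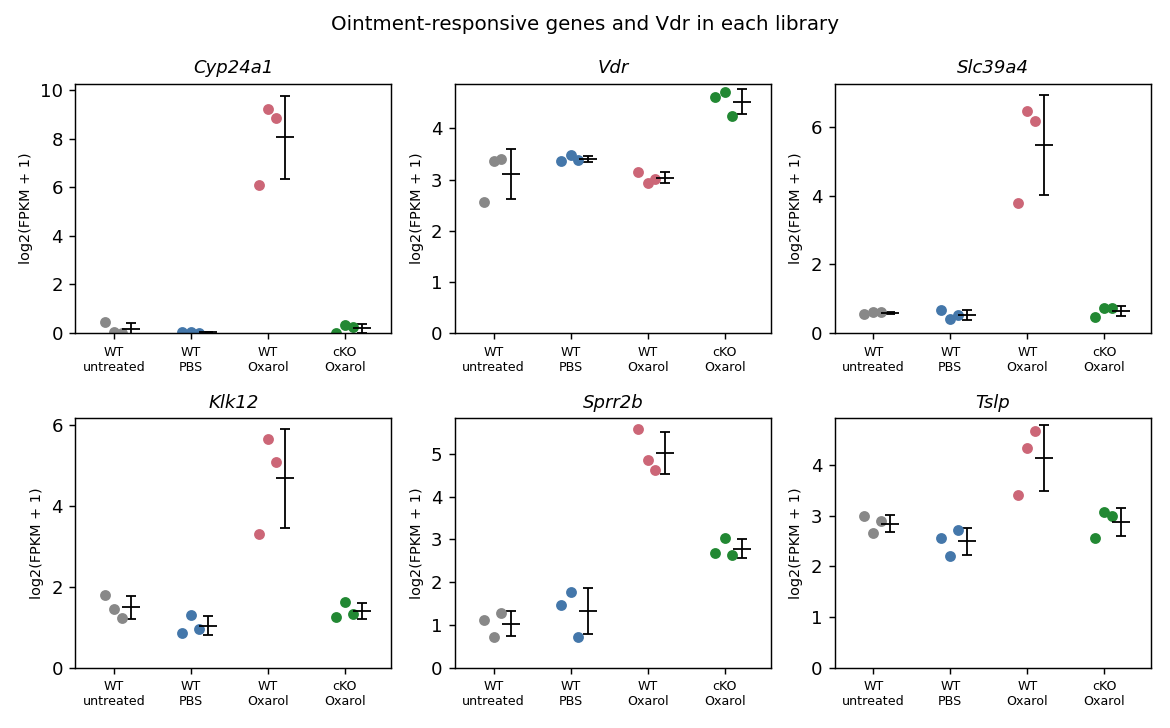
Values of 6 genes in each of the 12 libraries, as log2(FPKM + 1), by group (horizontal axis); points are libraries and bars the mean ± SD of 3. Cyp24a1, Slc39a4 and Klk12 were high in the 3 WT_Oxarol libraries, and Vdr was highest in the libraries labelled VDRcKO_Oxarol.

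The second comparison set the ointment-treated libraries labelled VDRcKO_Oxarol against ointment-treated wild type, the question being which responses differ with the receptor deleted in keratinocytes. Genes that rose with the ointment in wild type were lower: Cyp24a1 by -7.85 ± 0.62 (SE, log2, n = 3 and 3; adjusted p = 0.000689), Slc39a4 by -4.83 ± 0.53, Klk12 by -3.28 ± 0.46, Klk13 by -2.43 ± 0.41, Klk6 by -1.80 ± 0.35 and Tslp by -1.26 ± 0.28 (adjusted p = 0.0212). Sprr2a2 and Sprr2b were lower by -2.32 ± 0.43 and -2.23 ± 0.30. Slc37a2 (0.49 ± 0.14) and Rptn (0.53 ± 0.10), which also rose with the ointment in wild type, were higher still in VDRcKO_Oxarol, although these calls were lost under 18 and 6 of 25 alternatives, and Lipn, which fell in wild type, was higher by 0.77 ± 0.18. There was no untreated or PBS group of this genotype, so genotype and response cannot be separated.

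Hair shaft and root sheath genes were far higher in VDRcKO_Oxarol: 16 of 20 measured hair follicle genes rose and 0 fell (18 adjusted over the list alone), with a median of 3.68 (camera adjusted p = 2.49e-07; adjusted p = 0.822 with an estimated correlation). Examples were the hair keratins Krt35 (2.88 ± 0.51), Krt83 (3.86 ± 0.73), Krt85 (3.10 ± 0.64), and the inner root sheath keratins Krt25 (3.67 ± 0.72) and Krt71 (5.54 ± 1.58). Keratin-associated protein genes filled the largest increases: Krtap15 (6.18 ± 1.70), Krtap16-5 (6.09 ± 1.71), Krtap16-10b (5.87 ± 1.68), Krtap14 (5.61 ± 1.54), Krtap16-7 (5.53 ± 1.58) and Krtap16-3 (5.53 ± 1.48), with Gm11562 (5.10 ± 1.49) and Gm11938 (5.08 ± 1.34). Gm9846 rose by 9.21 ± 2.06, but stood at 891 FPKM in WT_untreated replicate 3 as well. These families hold near-identical members, so the split of reads between them is uncertain. With the hair follicle level as a term, Krt71, Gm11562, Gm11938 and the 6 Krtap genes named here turned sign. That term is the mean of the hair follicle list and follows the groups, so it removes changes of hair genes by construction and does not measure how firm they are. The calls of these genes were lost under 9 to 13 of 25 alternatives besides. The mean log2 level of the hair follicle list was 5.07, 4.42 and 3.48 in the 3 VDRcKO_Oxarol libraries and 0.718 to 3.54 in the 9 wild type libraries, with WT_PBS replicate 3 highest.

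Terminal differentiation genes moved in both directions. Of 32 measured cornified envelope and differentiation genes, 9 rose and 1 fell (14 and 1 adjusted over the list alone), among them Casp14, the protease of cornifying cells (2.06 ± 0.18), Cst6 (1.20 ± 0.19) and involucrin Ivl (1.03 ± 0.19), but the list did not pass camera (adjusted p = 0.176). In the Sprr family 5 of 11 fell and 2 rose: Sprr4 rose by 3.92 ± 0.46 and Sprr1a by 1.16 ± 0.23, while Sprr1b changed by -1.70 ± 0.49 (median -1.23, camera adjusted p = 0.00526; adjusted p = 0.822 with an estimated correlation). The Sprr1b call was lost under 13 of 25 alternatives. The Sprr list did not pass with quantile normalization, with a filter of 5 FPKM (median -1.59) or with the hair follicle level as a term (-0.15, and -0.15 for Sprr1b). Of 24 kallikreins and inhibitors 5 fell and 1 rose (camera adjusted p = 0.0371; adjusted p = 0.849 with an estimated correlation), including Serpinb2 (-1.10 ± 0.16). The list median of -0.08 turned to 0.03 with the library series as a term and to 0.11 with the hair follicle level as a term. The list did not pass under either scaling alternative or without WT_untreated replicate 1 (-0.08), WT_Oxarol replicate 1 (-0.05) or VDRcKO_Oxarol replicate 1 (-0.06), and its median was -0.12 without VDRcKO_Oxarol replicate 3. The beta-defensins split, Defb6 rising by 2.56 ± 0.30 and Defb1 by 0.61 ± 0.13 while Defb14 changed by -1.42 ± 0.26. Krt17 and Krt75, from the list of activated-epidermis genes, rose by 1.30 ± 0.18 and 1.22 ± 0.34. The Krt75 call was lost under 12 of 24 alternatives, and its change was 0.09 with the hair follicle level as a term. Among wild type libraries, Krt75 was highest in WT_untreated replicate 3 and WT_PBS replicate 3 (2.5 and 2.7 FPKM, 1.0 to 1.8 in the others). Those libraries also had the highest hair follicle level of the wild type, so the Krt75 rise cannot be told apart from hair follicle content. The list of 19 genes went both ways, with 3 higher (Krt17, Krt75 and S100a3, the last by 3.80 ± 0.74) and 2 lower (4 and 6 adjusted over the list alone). It did not pass (camera adjusted p = 0.429). Whether the S100a3 rise follows hair follicle content was not examined. The interleukin Il18 rose by 1.08 ± 0.16 and the interleukin-1 antagonist Il1rn fell by 0.47 ± 0.13, the Il1rn call being lost under 10 of 25 alternatives. Bglap, osteocalcin, a receptor target in bone, fell by 1.26 ± 0.25, and the fatty acid elongase Elovl6 fell by 0.74 ± 0.12.

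Markers of other tissue components also stood higher in VDRcKO_Oxarol than in WT_Oxarol. Of 20 macrophage and monocyte genes 10 rose, among them Emr1 (0.97 ± 0.15) and Mrc1 (0.53 ± 0.08), with a list median of 0.48 (camera adjusted p = 2.7e-05). Of 15 cartilage genes 8 rose, led by the cartilage collagen Col2a1 (1.91 ± 0.23) and Col11a2 (1.11 ± 0.19), and of 16 fibroblast genes 7 rose, including Col3a1 (1.46 ± 0.28), Fbn1 (0.74 ± 0.13) and Col5a1 (0.83 ± 0.15), with camera adjusted p = 2.7e-05 and 0.000138. Of 18 interferon-induced genes 5 rose, including Oasl1 (0.98 ± 0.17), Oas1a (1.17 ± 0.24), Usp18 (0.88 ± 0.19) and Irf9 (0.55 ± 0.12), and all 18 had a change above 0 (median 0.63, camera adjusted p = 2.7e-05). Cd3e and Cd3g, CD3 subunits of the T cell receptor complex, rose by 0.62 ± 0.12 and 0.63 ± 0.14 (3 of 16 in the list, camera adjusted p = 0.0104). Cd3e stood at 9.12 to 10.6 FPKM in VDRcKO_Oxarol and at most at 8.52 in wild type. Cd3g stood at 24.6 to 26.9 FPKM there, within the range of WT_untreated (17.2 to 27.1). Endothelial genes had 2 of 16 called (camera adjusted p = 0.0173), a list that did not pass without WT_Oxarol replicate 1 (median 0.36) or with the library series as a term. Of 31 cell cycle genes 4 fell: Pcna (-0.54 ± 0.12), Mcm4 (-0.42 ± 0.12), Mcm6 (-0.46 ± 0.14) and Prc1 (-0.70 ± 0.19), with camera adjusted p = 1.25e-06; the calls of Mcm6, Prc1 and Mcm4 were lost under 13, 11 and 10 of 25 alternatives. The cell cycle list median of -0.33 became -0.04 with the hair follicle level as a term, where the list did not pass. With an estimated correlation the adjusted p was 0.822 for the macrophage, cartilage, fibroblast, interferon, T cell and cell cycle lists and 0.853 for endothelium. Other called genes were the immediate early genes Egr2 (1.50 ± 0.16) and Klf2 (1.46 ± 0.36), the wound genes Fn1 (1.00 ± 0.17) and Mmp12 (1.58 ± 0.31), Epcam (0.83 ± 0.17), Ciita (0.49 ± 0.11), the thymic stromal lymphopoietin receptor chain Crlf2 (0.67 ± 0.15) and Ccl8 (0.79 ± 0.21). Epcam stood at 48.2 to 58.4 FPKM in VDRcKO_Oxarol, near WT_untreated (48.7 to 55.0), and was low in WT_Oxarol (22.6 to 41.4). The Ccl8 and Klf2 calls were lost under 10 and 7 of 25 alternatives, and those of Ciita and Crlf2 under 7 and 6 of 24. The immediate early and wound lists did not pass camera (adjusted p = 0.241 and 0.805).

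Short RNA genes made up most of the largest decreases. Mir181b-2, Mir3091, Snord123, Snord35a, Snord33, Mir20a, Mir18 and Snora33 were called lower, and each was listed at 0 in all 3 VDRcKO_Oxarol libraries. Of 24 alternatives, 14 ended the call of Snord123, 12 that of Snord33, 11 that of Mir20a, 10 those of Mir18 and Snord35a, 7 that of Mir3091, 5 that of Mir181b-2 and 1 that of Snora33. The alternatives reuse the same listed zeros, so these counts do not show that a call rests on enough reads. Snora33 stood at 17.8, 25.9 and 42.5 FPKM in WT_Oxarol replicates 1, 2 and 3, highest in the shallowest library (0.065 of the deepest). A few reads per library would give such values. Of 180 such genes tested, 11 were called lower and 1 higher, against 623 lower and 1225 higher of all 14059 genes tested. Calls in both directions together were thus not more frequent among short RNA genes than over all genes. Lower calls taken alone were somewhat more frequent among short RNA genes (11 of 180) than over all genes (623 of 14059).

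Limma called 1848 genes, 1225 higher and 623 lower, 285 of them by at least 2-fold on the log2(FPKM + 1) scale; 42.2% of genes had no overlap between groups, against 10% by chance. The direction split depended on scaling: quantile normalization gave 820 higher and 1292 lower of 2112, moving the median of all genes from 0.08 to -0.04, and median-of-ratios scaling gave 854 higher and 1097 lower. The library series as a term left 283 calls, the hair follicle level as a term left 1, and the count was 322 without WT_Oxarol replicate 2, 1061 and 1045 without replicates 1 and 3, 502, 504 and 760 without VDRcKO_Oxarol replicates 1, 2 and 3, 1214 without WT_PBS replicate 1 and 3433 without WT_untreated replicate 1.

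**Figure D2:**
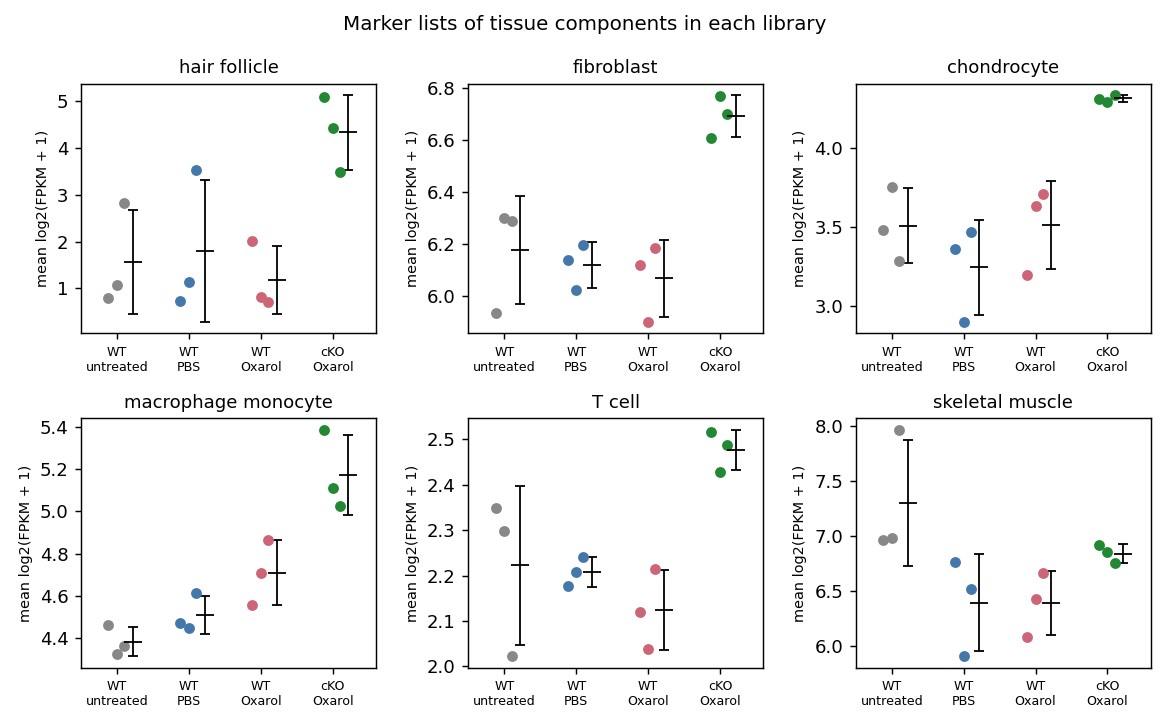
Mean log2(FPKM + 1) over the measured genes of 6 marker lists in each library, by group (horizontal axis); points are libraries and bars the mean ± SD of 3. The hair follicle list stood at 3.48 to 5.07 in VDRcKO_Oxarol and spread from 0.718 to 3.54 over the wild type libraries.

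**Figure D3:**
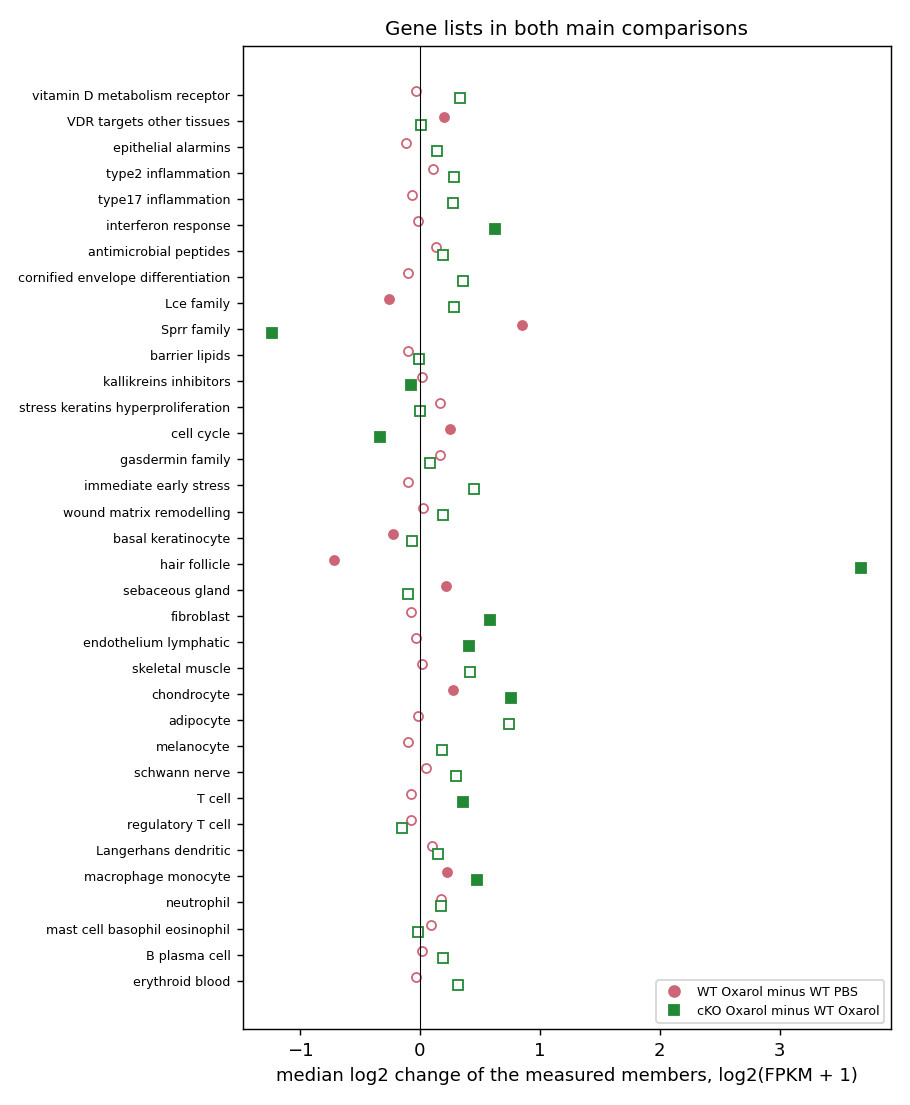
Median log2 change of each of the 35 lists between WT_Oxarol and WT_PBS (circles) and between VDRcKO_Oxarol and WT_Oxarol (squares); filled symbols had a camera adjusted p under 0.05 at the preset correlation. The Sprr list went from 0.86 to -1.23 and the hair follicle list from -0.72 to 3.68 between the comparisons, which share the WT_Oxarol libraries.

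Of the 43 genes called with the ointment in wild type, 24 were called in the opposite direction between VDRcKO_Oxarol and WT_Oxarol. These were 21 of the 35 that rose, including Cyp24a1, Slc39a4, Klk12, Sprr2b and Tslp, and 3 of the 8 that fell, Scgb1a1, Lipn and Slc6a14. Independent lists of these sizes would share 1.55 and 0.697 genes. At an unadjusted p under 0.05 in both comparisons, 342 genes changed in opposite directions, against a mean of 168.2 in 20 simulations with no effect and the shared WT_Oxarol libraries. The simulations held no effect in either comparison, whereas limma put 4531 genes at an unadjusted p under 0.05 between VDRcKO_Oxarol and WT_Oxarol. Unrelated changes could therefore give more pairs than simulated, so the excess over 168.2 does not measure a link. The 3 WT_Oxarol libraries could not be split. Against WT_PBS, 14 of the 35 were also called higher in VDRcKO_Oxarol, among them Krt1 (2.17 ± 0.21), Slc37a2 (1.34 ± 0.14), Rptn (1.25 ± 0.10), Sprr2a2 and Sprr2b; independent lists would share 3.77. These comparisons share the WT_PBS libraries: at an unadjusted p under 0.05 in both, 491 genes changed in the same direction against a mean of 170.2 simulated with no effect. The same limit holds here, since limma put 4818 genes at an unadjusted p under 0.05 between VDRcKO_Oxarol and WT_PBS. The overlap was 142 with array weights and 0 with only the groups compared in each fit or with the hair follicle level as a term. It was 10 and 13 without WT_PBS replicates 1 and 3, 76, 12 and 8 without WT_Oxarol replicates 1, 2 and 3, and 14 and 15 without VDRcKO_Oxarol replicates 1 and 2.

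The comparison of PBS with no treatment addressed handling and the application of PBS; the ointment base was not tested in any group. Genes of neutrophils and their chemoattractants, and genes of activated epidermis, were higher after PBS as lists. All 14 measured genes of the neutrophil and chemoattractant list had a change above 0 (median 0.86, 9 adjusted over the list alone, camera adjusted p = 1.29e-12), as did 18 of 19 activated-epidermis genes (median 0.74, 10 adjusted over the list alone, camera adjusted p = 7.42e-13). Both held with an estimated correlation (camera adjusted p = 0.0203 and 0.0325), as did wound and matrix genes (adjusted p = 0.0325). These lists are not separate results, since they share members as written. S100a8 and S100a9 are in the neutrophil and the activated-epidermis lists, and Mmp8 and Mmp9 in the neutrophil and the wound lists. Striated muscle genes had a median of -0.95, with 18 of 20 lower adjusted over the list alone (camera adjusted p = 8.11e-17; adjusted p = 0.277 with an estimated correlation), and -0.60 without WT_untreated replicate 3. Adipocyte genes had a median of -0.60 (adjusted p = 0.617 with an estimated correlation) that rested on the same library: without it the median was -0.08 and the list did not pass (camera adjusted p = 0.634). Over all genes no member of these lists passed. Among the genes with the smallest p, the neutrophil chemoattractant Cxcl5 differed by 1.56 ± 0.20 (adjusted p = 0.0660), Chi3l3 by 1.87 ± 0.29 (adjusted p = 0.167), 2610528A11Rik by 2.35 ± 0.31 (adjusted p = 0.0660) and Skint7 by -0.86 ± 0.12 (adjusted p = 0.108). The stefin Stfa1 differed by 2.55 ± 0.59 (adjusted p = 0.430).

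Limma called 1 gene between WT_PBS and WT_untreated, Mir1224, listed at 0 in all untreated libraries, with 1312 genes at an unadjusted p under 0.05. As given above, the Mir1224 values may rest on very few reads. Limma called 0 genes with short RNA genes left out (1318 at an unadjusted p under 0.05), 13 in the first library series alone, 6 without WT_PBS replicate 3 and 2 without VDRcKO_Oxarol replicate 1 or 2.

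Against untreated wild type skin, Cyp24a1 was higher after the ointment by 7.89 ± 0.62 (SE, log2, n = 3 and 3, limma adjusted p = 0.000346), Slc39a4 by 4.89 ± 0.53 and Sprr2a2 by 4.50 ± 0.43. The stefin Stfa1 was higher by 5.03 ± 0.59, but it already differed by 2.55 ± 0.59 between PBS and no treatment (limma, adjusted p = 0.430). The keratinocyte chemokine Ccl27a fell by 1.66 ± 0.26 from 256.9 ± 16.6 FPKM (SD, n = 3), Scgb1a1 fell by 1.81 ± 0.23, Ifitm6 fell by 1.47 ± 0.29 and Clca2 fell by 1.34 ± 0.26; the calls of Clca2 and Ifitm6 were lost under 16 and 15 of 26 alternatives. Of 19 activated-epidermis genes 10 rose (median 1.57, camera adjusted p = 4.42e-07, adjusted p = 0.161 with an estimated correlation). Of 14 genes of neutrophils and their chemoattractants 4 rose (median 0.94, camera adjusted p = 0.0438 with an estimated correlation). Both lists were also higher after PBS than without treatment, as given above, so these medians do not set the ointment apart from handling. All 31 cell cycle genes had a change above 0 and 2 rose (median 0.62, 25 adjusted over the list alone; adjusted p = 0.35 with an estimated correlation). PBS against no treatment gave this list a median of 0.36, also with all 31 above 0 (camera adjusted p = 1.12e-10; adjusted p = 0.482 with an estimated correlation), which was 0.21 without WT_untreated replicate 3 and 0.20 without WT_PBS replicate 2. Striated muscle genes had a median of -0.89 against untreated skin (adjusted p = 0.374 with an estimated correlation), and -0.56 without WT_untreated replicate 3. Adipocyte genes had a median of -0.53 (adjusted p = 0.688 with an estimated correlation), which was -0.86 without WT_untreated replicate 2 and -0.06, no longer passing, without replicate 3. Snord53 was listed at 0 in all untreated libraries and Mir744 in all WT_Oxarol libraries, and both were called, Snord53 losing its call under 15 of 25 alternatives. The Mir744 call may rest on very few reads, as given above.

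Limma called 184 genes here, 139 higher and 45 lower. A fit of these 6 libraries alone called 12, the first library series alone called 26, and the count was 49 without WT_untreated replicate 3, 66 without WT_PBS replicate 1, 34 and 35 without WT_Oxarol replicates 2 and 3, and 120, 74 and 95 without VDRcKO_Oxarol replicates 1, 2 and 3.

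Between VDRcKO_Oxarol and WT_PBS, where genotype and treatment both differ, Cyp24a1 changed by 0.16 ± 0.62 (SE, log2, n = 3 and 3; limma adjusted p = 0.876; 95% interval -1.22 to 1.54) while Vdr rose by 1.11 ± 0.21. Hair genes again led: Krtap8-1, Krtap11-1, Krtap4-8 and Krt81 rose by 4.09 ± 1.16, 4.03 ± 1.24, 3.86 ± 1.11 and 3.53 ± 0.98, and Gm9846 by 9.40 ± 2.06. The calls of Krtap11-1, Krtap4-8, Krtap8-1 and Krt81 were lost under 16, 12, 11 and 10 of 25 alternatives. Of 20 macrophage genes 16 rose, and of 15 cartilage genes 10 rose (adjusted p = 0.741 for both lists with an estimated correlation). Mir181b-2, Mir3091, Mir425 and Mirlet7c-2 were called lower and listed at 0 in all VDRcKO_Oxarol libraries, and Mir3074-2 was called lower with 2 of them at 0. Of 24 alternatives, 11 ended the call of Mirlet7c-2, 10 that of Mir425, 8 that of Mir3074-2, 6 that of Mir3091 and 2 that of Mir181b-2.

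Limma called 2286 genes between these groups, 1514 higher and 772 lower; quantile normalization turned the split to 968 higher and 1620 lower, moving the median of all genes from 0.09 to -0.04, and median-of-ratios scaling to 1079 higher and 1316 lower. The library series as a term left 611 calls, the hair follicle level as a term left 41, and the count was 543 and 646 without WT_PBS replicates 1 and 2, 889, 959 and 1229 without VDRcKO_Oxarol replicates 1, 2 and 3 and 3875 without WT_untreated replicate 1.

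Changes from the ointment in wild type (against untreated) were set beside the differences of VDRcKO_Oxarol from WT_PBS, a pair of comparisons with no library in common. The second is not the ointment response of that genotype. Genotype differs there as well as treatment, and no untreated or PBS group of the genotype exists. Across all 14059 tested genes, Pearson's r was -0.02, Spearman's rho 0.05 and the covariance -0.00588, and 7291 genes (51.9%) had the same sign. Across the 184 genes called in wild type, r was 0.41, rho 0.49, the covariance 0.427 and the slope 0.176, and 139 genes (75.5%) had the same sign. Within the 139 called higher, r was 0.13, rho 0.31 and the slope 0.0563, and within the 45 called lower, r was 0.64 and rho 0.03, so the pooled values include the gap between the higher and the lower genes. The 45 include Mir744, listed at 0 in all WT_Oxarol and VDRcKO_Oxarol libraries and possibly resting on very few reads in the others. Its change in wild type was -4.925, where the next largest named decrease was -1.81 (Scgb1a1), and r was not computed without it. These are correlations across genes, which are not independent replicates. The value over all genes ranged from -0.15 to 0.15 and that over called genes from 0.27 to 0.64 as single libraries were left out, the lowest of each without WT_untreated replicates 1 and 2 and the highest without WT_untreated replicate 3.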

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

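Alternatives with short RNA genes, abundant zeros or the hair follicle level were chosen after seeing the data, as was leaving out together WT_untreated replicate 3 and WT_PBS replicate 3, the control libraries with the highest hair follicle level (both hair-high controls below). Of 3338 values of named genes under the alternatives, 2581 kept their direction and side of the threshold, 721 no longer passed, 26 newly passed and 10 turned sign; of 1439 list medians the counts were 1293, 138, 0 and 8. The cause was not tested except where stated. Count tests were not run, since no read counts were recovered, and the first series alone gave no value for VDRcKO_Oxarol, which has no library in it. Read depth limits low genes most in WT_Oxarol replicate 3, at 0.065 of the deepest library.

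Calls between WT_Oxarol and WT_PBS (43) became 360 with array weights (177 higher, 183 lower), 8 in the first series, 21 without both hair-high controls, 0 in a fit of the 2 groups (limma, 1401 at an unadjusted p under 0.05, with fewer residual degrees of freedom) and 13 to 132 leaving out single libraries. Calls between VDRcKO_Oxarol and WT_Oxarol (1848) became 283 with the series term, 3648 with array weights, 1 with the hair follicle level as a term and 322 to 3433 leaving out single libraries. The hair follicle level raised the unscaled error of this comparison 1.61 times, since it follows the groups; there Cyp24a1 stood at -6.84 and Casp14 at 2.16, but neither passed (adjusted p = 0.105 for both; 9.02e-09 to 0.105 over the alternatives of Cyp24a1 and 0.000346 to 0.105 over those of Casp14). Calls between WT_PBS and WT_untreated (1) became 5 with a pseudocount of 0.1, 2 with no filter, 3 with the robust model, 6 with array weights, 13 in the first series, 0 without short RNA genes (limma, 1318 at an unadjusted p under 0.05), 2 with the hair follicle level, 10 without both hair-high controls, 6 in a fit of the 2 groups and 1 to 6 leaving out single libraries. Calls between WT_Oxarol and WT_untreated (184) became 90 with no filter, 561 with array weights, 26 in the first series, 55 without both hair-high controls, 12 in a fit of the 2 groups and 34 to 254 leaving out single libraries. Calls between VDRcKO_Oxarol and WT_PBS (2286) became 611 with the series term, 5427 with array weights, 41 with the hair follicle level, 3737 in a fit of the 2 groups and 543 to 3875 leaving out single libraries.

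The overlap of ointment calls with opposite calls in VDRcKO_Oxarol (24) became 142 with array weights, 0 with the hair follicle level, 14 without both hair-high controls, 0 in fits of the 2 groups and 8 to 76 leaving out single libraries. The correlation over all genes (-0.0243) became 0.0495 with the hair follicle level, 0.12 without both hair-high controls, 0.0854 with the control groups exchanged and -0.148 to 0.146 leaving out single libraries; that over called genes (0.406) became 0.574 with no filter, 0.527 with the robust model and 0.274 to 0.64 leaving out single libraries.

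With the series term, medians turned to 0.0295 for kallikreins between VDRcKO_Oxarol and WT_Oxarol and to 0.126 for the cell cycle between VDRcKO_Oxarol and WT_PBS, and Cyp24a1 turned to -0.0449 there. The hair follicle median between WT_Oxarol and WT_PBS turned to 0.532 in the first series and 0.244 without both hair-high controls, and ranged from -1.33 to 0.244 leaving out single libraries. With the hair follicle level as a term, which removes changes of hair genes by construction, changes between VDRcKO_Oxarol and WT_Oxarol turned to -0.90 for Krt71, -0.56 for Krtap15, -0.38 for Krtap16-5, -0.68 for Krtap16-10b, -0.50 for Krtap14, -0.67 for Krtap16-7, -0.0799 for Krtap16-3, -0.84 for Gm11562, -0.35 for Gm11938 and 0.112 for the kallikrein median, and the cell cycle median between VDRcKO_Oxarol and WT_PBS turned to 0.105. That median ranged from -0.278 to 0.0162 leaving out single libraries.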

Other observations

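The tests of library series and of varying hair follicle content behind the hair follicle genes, of swapped libraries and of exons outside the deleted part behind Vdr, and the depth tests without WT_PBS replicate 3 and with halved depths were chosen only after the values they rest on were seen. Marker lists of other tissue components gave further differences between VDRcKO_Oxarol and WT_PBS: 7 of 16 fibroblast genes were called higher (median 0.52, camera adjusted p = 0.00362; adjusted p = 0.741 with an estimated correlation), as were 6 of 21 Langerhans and dendritic cell genes (median 0.27, camera adjusted p = 0.0416; adjusted p = 0.897 with an estimated correlation). Of 9 regulatory T cell genes 3 were called lower there (median -0.23, camera adjusted p = 0.0302; adjusted p = 0.741 with an estimated correlation). The regulatory T cell list did not pass without WT_untreated replicate 1 (-0.23) or WT_PBS replicate 1 (-0.06), and was -0.39 and -0.11 without WT_PBS replicate 3 and VDRcKO_Oxarol replicate 3. The Langerhans and dendritic cell list did not pass without WT_untreated replicates 1 (0.27) and 2 (0.27), WT_PBS replicate 1 (0.23), WT_Oxarol replicate 3 (0.27) or VDRcKO_Oxarol replicate 1 (0.18). Of 18 interferon-induced genes 4 were called higher and all 18 had a change above 0 (median 0.70, camera adjusted p = 0.000727; adjusted p = 0.897 with an estimated correlation), with a median of 0.43 without VDRcKO_Oxarol replicate 1.

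Hair follicle genes stood higher in the VDRcKO_Oxarol libraries than in WT_Oxarol, by 3.15 ± 0.88 (SE) in mean log2 level over 20 genes. With library series as a term the difference was 2.30 (95% interval 0.217 to 4.38), which assumes the same series shift in every group. Within the second series, which holds all 3 VDRcKO_Oxarol libraries, the groups overlapped (3.48 in VDRcKO_Oxarol replicate 3, 3.54 in WT_PBS replicate 3), and 4 of 20 splits gave as large a difference (exact two-sided permutation p = 0.2, the smallest possible being 0.1). Library series and variation of hair follicle content between libraries therefore cannot be told apart from the genotype label, since the first series holds no VDRcKO_Oxarol library and the second only 3 of wild type. Hair cycle stage and age within the stated range also stay open, as untested.

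The Vdr value was higher in the libraries labelled VDRcKO_Oxarol. A swap with WT_Oxarol was argued against, since the highest Cyp24a1 value there was 0.271 FPKM against a lowest of 66.2 in WT_Oxarol; an exchange with samples outside the series was not tested. Hair follicle content was argued against as the whole cause, if the relation is linear on the log2 scale. Its slope within the wild type groups (0.0951 ± 0.102, SE) predicted a rise of 0.299 (95% interval -0.528 to 1.13) against the observed 1.49. The observed minus predicted rise was 1.19 (0.209 to 2.17). The level reached 3.54 in wild type and 5.07 in VDRcKO_Oxarol, so the prediction extends beyond the wild type range and its interval does not cover a curved relation. Reads from exons outside the deleted part cannot be told apart from a rise of the whole transcript, since the value covers the gene; the observed 1.49 is all there is. A rise in cells without Cre is a candidate explanation that was not tested.

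Of the 180 microRNA and snoRNA genes tested, 11 were called lower in VDRcKO_Oxarol than in WT_Oxarol, and a mean of 63.1% of the 180 were listed at 0 in VDRcKO_Oxarol. The wild type relation to read depth predicted 42.8% (95% prediction interval 30.3 to 55.3), 20.3 percentage points below the observed share, and 18.8 below it (7.92 to 29.7) without WT_PBS replicate 3. That bound took the depths as exact, but each could be off by a factor of 2, and with the VDRcKO_Oxarol depths halved the prediction was 55.1% (41.4 to 68.8), which covers the observed share. Read depth therefore stays open, and the genotype cannot be told apart from it. A difference in fragment length or RNA recovery between library series may add to it. In the wild type libraries of the second series the share was 40% (WT_untreated replicate 3, at 0.090 of the deepest library), 5% (WT_PBS replicate 3) and 54.4% (WT_Oxarol replicate 3, at 0.065), against 58.3% to 66.1% in VDRcKO_Oxarol (0.081 to 0.118), but single libraries with uncertain depths do not exclude it.

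With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. Each split other than the real one mixes both groups on each side, so a difference between them enters the spread and lowers the calls. The counts of the other splits therefore do not show how many calls chance gives. All VDRcKO_Oxarol libraries are in the second series, so a batch could also set the real split apart there. The real split called 43 genes between WT_Oxarol and WT_PBS against at most 3 in another, 1848 against 3 between VDRcKO_Oxarol and WT_Oxarol, 184 against 3 between WT_Oxarol and WT_untreated, and 2286 against 1 between VDRcKO_Oxarol and WT_PBS; in each of these 1 split, the real one, called as many. Between WT_PBS and WT_untreated 6 of 10 splits called at least 1 gene, with 3 at most.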
